A study of Homo sapiens with 12 samples.

How the data were processed

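Poly-A selected RNA from differentiated human bronchial epithelial cultures was sequenced on an Illumina HiSeq instrument, per the labels, from 12 samples in 3 groups of 4 (acetone vehicle, BAP and DBC). The authors deposited 1 file per sample with FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene. Per the submitters' processing notes, cutadapt 1.8.1, Bowtie2, TopHat2 2.1.1 and Cuffdiff 2.2.1 were used with the GRCh38 build. Their order and settings, the annotation release, the use of strand in counting and any scaling between libraries are not given in the sources used here. Each file held 60487 gene rows, and 91 further rows that repeated a gene identifier with no value were dropped. In 28 rows a spreadsheet had turned the symbol into a date, and these were restored from the Ensembl identifier. Of the identifiers, 94.2% were found in GENCODE v29, which supplied coordinates, biotypes and transcript lengths on the same build. The 548 rows of chromosome Y genes, XIST and TSIX were left out. Gene symbols are those of the files.

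Depth was read from the low values, which in genes of 1500 to 8000 nt were whole multiples of the value of 1 fragment. Between 94.4% and 96.1% of values worth at most 10 fragments lay within 0.1 of a whole number of fragments, and the step gave 5420908 to 10024309 fragments per library, up to any scaling by the authors. Single-fragment steps are large for short genes, so FPKM of genes under 200 nt are coarse and depend on the length correction. Exact zeros may be failed estimates, and such genes are described as listed at 0. Ribosomal protein genes have many pseudogene copies, and fragments shared among copies or among overlapping genes may have been divided by the authors' counting, which leaves such levels uncertain.

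Genes with a mean of at least 1 FPKM over the 12 libraries were tested (14514 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a linear model of the group means over all 12 libraries, moderated variances with a mean-variance trend, and Benjamini-Hochberg adjustment per comparison at 0.05 (two-sided). Adjusted p values of genes are from limma. Gene lists written from general knowledge were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 69 tests (23 of 27 lists with at least 5 tested members, 3 comparisons). Of these, 38 passed with the preset correlation and 0 with a correlation estimated per list, where the lowest adjusted p was 0.452 and 6 tests had an unadjusted p under 0.05. The lists cover the AHR battery, xenobiotic oxidation, conjugation and efflux, NRF2, p53, excision repair, cell division, cytokines, interferon, ciliated, secretory, basal, squamous, rare epithelial, fibroblast, leukocyte and endothelial markers, junctions, desmosomes, matrix, unfolded protein response, heat shock, metallothioneins, cholesterol, glycolysis, immediate early, mitochondrial and ribosomal genes. CBR1, IL33, NQO1 and SLC7A11 each belong to 2 lists.

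Named genes are the 10 largest increases and the 10 largest decreases per comparison among genes that passed with no overlap between groups, 9 fixed markers (CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1, CDKN1A, MDM2 and GDF15), and up to 4 members with the smallest p of each list. Rows without a gene symbol were skipped, and some genes that the rule selects are left out of the text. The groups, tests, lists, this rule and most of the alternatives were fixed before the data were examined. Examples of genes shared by both compounds or changed in opposite directions were chosen after their values were seen.

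The model was tested on simulated data with 200 of the 14514 genes changed. Of 100 genes changed 2-fold, 64% (BAP versus vehicle), 65% (DBC versus vehicle) and 51% (DBC versus BAP) were recovered, and of 100 changed 4-fold 90%, 89% and 91%, with 6.1%, 6.1% and 5.96% false genes among the calls. The simulated values were normal and independent between genes, with the fitted spread of each gene the same in every group. Real genes move together and real groups may differ in spread, so these shares do not measure false calls in the real data. Overlap between the vehicle comparisons was set against 100 simulated sets of unchanged groups. Alternatives covered the pseudocount, the filter, the scaling, the model and leaving out each library, and 2 were chosen after seeing the data: only protein-coding genes of at least 200 nt, and library sums set equal over genes of at least 200 nt. Nothing in the labels says whether replicates came from separate donors or cultures, so p values measure the spread between these samples, which may be technical. The library index order follows the groups, and no batch label is given, so a batch difference between the groups cannot be told from a difference due to treatment.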

Results

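Human bronchial epithelial cells from primary culture, differentiated on porous inserts at the air-liquid interface, were profiled by RNA sequencing. Such cultures hold ciliated, secretory and basal cells under an upper surface exposed to air. The upper surface was treated for 48 h with benzo[a]pyrene (BAP, 500 µg/ml, 19.80 nmol), with dibenzo[def,p]chrysene (DBC, 10 µg/ml, 0.35 nmol) or with the acetone vehicle alone. Both compounds are polycyclic aromatic hydrocarbons formed in combustion. DBC, also called dibenzo[a,l]pyrene, carries an additional fused benzene ring compared with BAP. Each group had 4 libraries of poly-A selected RNA. The deposited FPKM implied 6237807 to 10024309 fragments per vehicle library, 6633762 to 9158529 per BAP library and 5420908 to 6623951 per DBC library. Within a group, libraries correlated at 0.932 to 0.957 (vehicle), 0.917 to 0.934 (BAP) and 0.95 to 0.959 (DBC) across the 14514 tested genes on the log2(FPKM + 1) scale. Group values below are mean FPKM ± SD over 4 libraries unless stated otherwise. Changes are differences of log2(FPKM + 1), which understate the change of genes near 1 FPKM.

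The first comparison asked what 48 h of BAP changed relative to vehicle. ALDH3A1, an aldehyde dehydrogenase induced through the aryl hydrocarbon receptor (AHR), rose from 43 ± 6.61 to 245 ± 143 FPKM (log2 change 2.27, SE 0.35, adjusted p = 0.00151). NQO1, a quinone reductase, rose from 468 ± 76.5 to 926 ± 201 FPKM (log2 change 0.97, SE 0.19, adjusted p = 0.00452). CYP1A1, the monooxygenase that starts the oxidation of BAP, averaged 179 ± 125 FPKM after BAP and 9.04 ± 3.51 in vehicle (log2 change 3.39, SE 0.86, adjusted p = 0.0152). CYP1B1, a related monooxygenase, averaged 622 ± 382 and 194 ± 44.9 FPKM (log2 change 1.42, SE 0.42, adjusted p = 0.0302).

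The rise of both monooxygenases was seen in 3 of the 4 BAP libraries. CYP1A1 stood at 301, 182 and 224 FPKM in BAP replicates 1, 2 and 4 and at 6.96 in replicate 3, inside the vehicle range of 4.76 to 13.3. CYP1B1 was at 638, 1097 and 592 FPKM in the same 3 libraries and at 163 in replicate 3. Without that library the CYP1A1 change was 4.60 (SE 0.27, adjusted p = 1.38e-05) and the CYP1B1 change 1.97 (SE 0.22, adjusted p = 0.00121). TIPARP, another AHR target, averaged 130 ± 67.2 FPKM against 101 ± 17 (log2 change 0.17, 95% interval -0.61 to 0.95, adjusted p = 0.781), with 41 in replicate 3. Without that library its change was 0.64 (adjusted p = 0.0311). Over the 8 fits that leave out 1 library, CYP1A1 passed in 6 (adjusted p 1.38e-05 to 0.0545), CYP1B1 in 2 (0.00121 to 0.0849) and ALDH3A1 and NQO1 in 8. With only the BAP and vehicle libraries in the fit, CYP1A1 (adjusted p = 0.0576) and CYP1B1 (adjusted p = 0.091) did not pass. AHRR, the AHR repressor, lay below the expression filter, at 0 to 1.44 FPKM in the BAP libraries and 0.0924 to 0.475 in vehicle. CYP1A1 lies on chromosome 15 (74719542 to 74725610, GRCh38), CYP1B1 on chromosome 2 (38066973 to 38109902), ALDH3A1 on chromosome 17 (19737984 to 19748943) and NQO1 on chromosome 16 (69706996 to 69726951). CYP1B1 overlaps RMDN2 and the antisense gene CYP1B1-AS1 on the other strand, so fragments of these genes may be shared where strand was not used in counting. It also overlaps RMDN2-AS1 on its own strand, where fragments may be shared in either case.

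**Figure D1:**
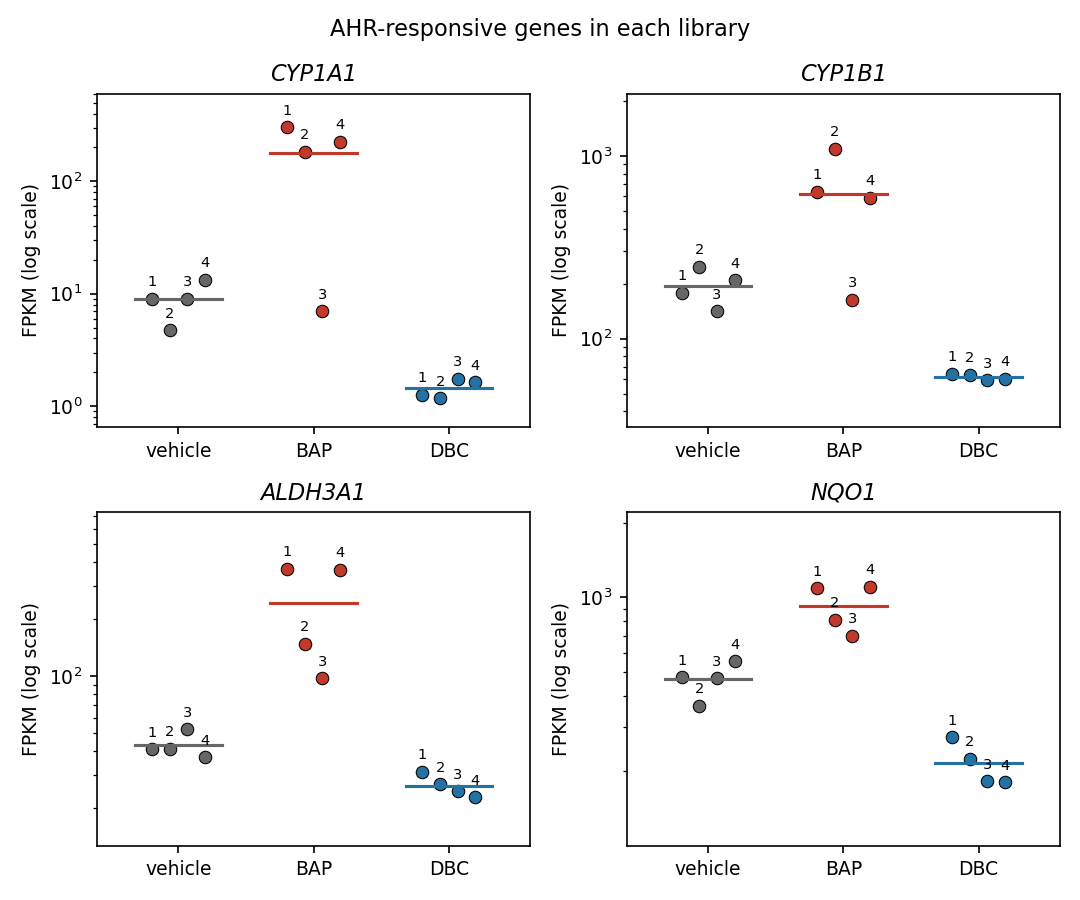
FPKM (log axis) of 4 AHR-responsive genes in each of the 12 libraries, numbered by replicate, with a horizontal line at each group mean. BAP replicate 3 lies at 6.96 FPKM of CYP1A1 while the other BAP libraries lie at 182 to 301, and all DBC libraries lie below all vehicle libraries for the 4 genes.

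As a group, 4 of the 12 tested AHR battery genes rose after BAP, 1 fell (EREG, a growth factor, from 190 ± 32.7 to 94.3 ± 61 FPKM) and 7 did not pass. Adjusted over the list alone the counts were also 4 and 1. The list test gave an adjusted p of 0.0933, and an adjusted p of 0.677 with an estimated correlation. Without BAP replicate 3, 6 members were higher and 0 lower, and the list passed (adjusted p = 0.000488), while EREG no longer did (adjusted p = 0.0658). The log2 mean of the AHR list was 5.53 in that library and 6.80 to 6.97 in the other BAP libraries. Leaving out the library lowest on the list favours a pass. With all libraries kept the AHR list passed after quantile normalization or with a mean of at least 5 FPKM (adjusted p = 0.0274 and 0.0497). Among 28 genes of xenobiotic oxidation and hydrolysis, 7 rose and 2 fell (8 and 2 adjusted over the list alone; list adjusted p = 0.00365, and adjusted p = 0.452 with an estimated correlation). The log2 mean of that list was 4.73 in BAP replicate 3, 4.96 to 5.12 in the other BAP libraries and 4.56 to 4.72 in vehicle. ALDH1A1, a retinal dehydrogenase, rose from 92.3 ± 8.28 to 247 ± 16 FPKM and EPHX1, the microsomal epoxide hydrolase, from 23.2 ± 1.72 to 49.8 ± 10.6. CYP3A5 fell from 73.2 ± 14 to 16.1 ± 2.16 FPKM. Conjugation and efflux genes had 5 of 21 higher, including GSTA1 and GSTA4, and 1 lower, SULT2B1 (6 and 1 adjusted over the list alone). The list adjusted p was 0.0551, and the adjusted p with an estimated correlation was 0.452. The conjugation list passed under 6 alternatives (adjusted p 0.0201 to 0.0489). These include leaving out vehicle replicate 1 (0.0239), BAP replicate 2 (0.0288) or BAP replicate 3 (0.0201). Its log2 mean was 3.63 and 3.60 in BAP replicates 2 and 3, inside the vehicle range of 3.46 to 3.67, 3.82 in replicate 1 and 4.06 in replicate 4. Of 25 NRF2 antioxidant genes, 5 rose, among them GCLM (42.9 ± 5.34 to 102 ± 45.1 FPKM) and CBR1 (12.9 ± 3.81 to 24.8 ± 5.19), and 1 fell (6 and 1 adjusted over the list alone). That list had an adjusted p of 0.113, and an adjusted p of 0.778 with an estimated correlation, while without BAP replicate 3 it passed with 10 higher and 1 lower (adjusted p = 0.000139). With all libraries kept it passed after quantile normalization, with library weights or with a mean of at least 5 FPKM (adjusted p = 0.0203, 0.04 and 0.0418). The log2 mean of the NRF2 list was 6.15 in BAP replicate 3, below the vehicle range of 6.45 to 6.69, and 6.87 to 7.06 in the other BAP libraries. Leaving out BAP replicate 3 therefore favours a pass of the NRF2 list too.

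Of 38 ciliated cell markers, 15 rose and 0 fell (23 and 0 adjusted over the list alone; list adjusted p = 2.64e-09). Their mean on the log2 scale was 4.55 and 4.56 in BAP replicates 2 and 4, inside the vehicle range of 3.66 to 4.58, 4.76 in replicate 1 and 5.32 in replicate 3. CCNO, a cyclin of centriole amplification, rose from 5.52 ± 0.542 to 20.1 ± 12 FPKM, EFCAB1 from 15.2 ± 5.69 to 36.6 ± 4.61 and CFAP43, an axonemal protein, from 39 ± 12.3 to 80.9 ± 14.1. Of 24 basal cell markers, 0 rose and 16 fell (0 and 17 adjusted over the list alone; list adjusted p = 4.06e-08). The integrin ITGA3 fell from 686 ± 81.9 to 215 ± 42.2 FPKM, the laminin chain LAMB3 from 423 ± 52 to 149 ± 53, and ITGA6 from 551 ± 84.9 to 272 ± 69.1. Both calls were lost with an estimated correlation, with an adjusted p of 0.452 for each. Of 27 secretory and mucous markers, 9 rose and 2 fell (9 and 2 adjusted over the list alone; list adjusted p = 0.00599, adjusted p = 0.528 with an estimated correlation). The immunoglobulin receptor PIGR rose from 644 ± 135 to 1240 ± 132 FPKM and MSMB from 168 ± 27.3 to 359 ± 123, while CLCA4 fell from 315 ± 67.3 to 98.8 ± 34.5. Without BAP replicate 3 the secretory list no longer passed (adjusted p = 0.0653), and its log2 mean in that library was 6.88, against 6.08 to 6.42 in the other BAP libraries and 5.79 to 6.23 in vehicle.

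Of 25 squamous genes, 11 fell and 2 rose (14 and 2 adjusted over the list alone; list adjusted p = 0.00152, adjusted p = 0.528 with an estimated correlation). The cornified envelope genes SPRR2D and SPRR2A fell from 22.4 ± 3.47 to 3.92 ± 2.13 and from 51.1 ± 15.3 to 11.4 ± 5.45 FPKM, and SERPINB4 rose from 8.02 ± 1.79 to 17.1 ± 3.39. The squamous mean on the log2 scale was 5.65 in BAP replicate 4, inside the vehicle range of 5.60 to 5.82, and 4.63 to 5.02 in the other BAP libraries. Of 13 desmosomal genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with the plaque protein PPL at 32.2 ± 5.61 against 65 ± 6.13 FPKM. Of 28 matrix remodelling and mesenchymal genes, 15 fell and 0 rose (17 and 0 adjusted over the list alone), including the protease MMP14 (131 ± 3.15 to 56.3 ± 12.6 FPKM) and the urokinase PLAU (691 ± 62.7 to 273 ± 73.1). List adjusted p values were 8.88e-05 for desmosomes and 2.7e-08 for matrix genes, and the adjusted p with an estimated correlation was 0.452 for each. Junction genes split, with 12 of 30 lower (F11R, 160 ± 13.1 to 91.8 ± 8.64 FPKM) and 5 higher (EPCAM, 68.2 ± 3.74 to 133 ± 12.6, and CLDN10, 35.9 ± 5.52 to 85.9 ± 17.7). Adjusted over the list alone the junction counts were 15 and 5. The list adjusted p was 0.02, and the adjusted p with an estimated correlation was 0.452. After quantile normalization the junction list no longer passed (adjusted p = 0.159). Of 5 fibroblast markers above the filter, 1 (FBLN1) was lower and 0 were higher (list adjusted p = 0.818), and FBLN1 no longer passed without BAP replicate 3 (adjusted p = 0.0501).

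**Figure D2:**
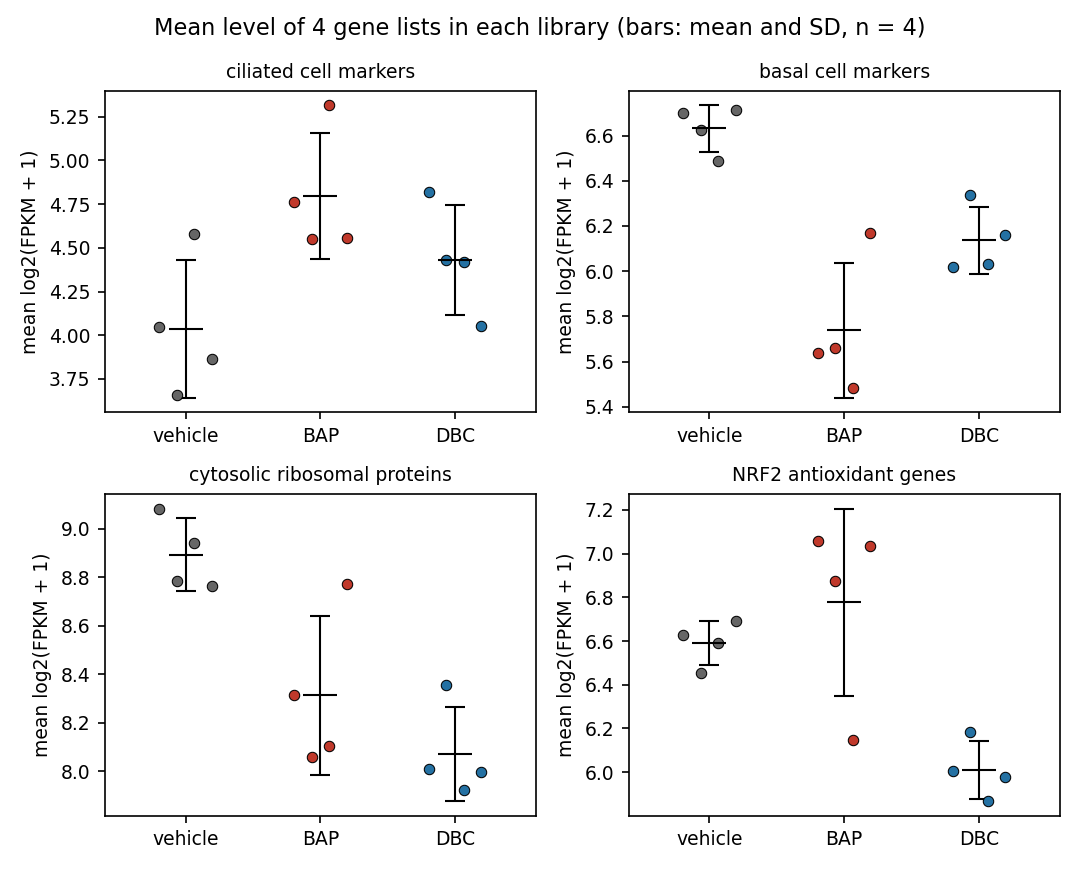
Mean log2(FPKM + 1) over the members of 4 gene lists in each library (points), with the mean and SD of each group of 4 (bars); the vertical axes do not start at 0. Ciliated markers averaged 4.04 in vehicle, 4.80 in BAP and 4.43 in DBC, and basal markers 6.63, 5.74 and 6.14.

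Damage-related and immune genes moved in part. Of 31 p53 target genes, 13 rose and 4 fell after BAP (15 and 5 adjusted over the list alone; list adjusted p = 0.00491, adjusted p = 0.452 with an estimated correlation). The mean of the list on the log2 scale was 4.80 in BAP replicate 3, 5.24 to 5.33 in the other BAP libraries and 4.80 to 4.91 in vehicle. ZMAT3 rose from 14.6 ± 0.579 to 28.4 ± 6.73 FPKM, TRIAP1 from 33.1 ± 3.95 to 70.3 ± 17, and PHLDA3 fell from 36.6 ± 7.19 to 19.1 ± 3.05. CDKN1A, the p21 cell-cycle inhibitor, was at 220 ± 45.5 against 215 ± 48.3 FPKM (log2 change 0.04, 95% interval -0.37 to 0.45, adjusted p = 0.9). MDM2, the p53 ubiquitin ligase, was at 309 ± 131 against 241 ± 45.3 (log2 change 0.27, 95% interval -0.29 to 0.83, adjusted p = 0.487), and its change was 0.54 without BAP replicate 3 (adjusted p = 0.0825). GDF15, a stress cytokine and p53 target, fell from 651 ± 144 to 363 ± 127 FPKM (adjusted p = 0.0236), and passed in 3 of the 8 fits that leave out 1 library (adjusted p 0.0131 to 0.0682). With only the BAP and vehicle libraries in the fit GDF15 did not pass (adjusted p = 0.0642). Of 27 interferon response genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone; list adjusted p = 0.00628, adjusted p = 0.452 with an estimated correlation), among them IFI27 (9.5 ± 5.09 to 28.9 ± 3.56 FPKM) and IFI44 (14.7 ± 1.53 to 24.8 ± 4.44). The 28 cytokine and NF-kB genes had 8 higher and 8 lower (8 and 11 adjusted over the list alone; list adjusted p = 0.911), with the chemokine CXCL6 at 57.1 ± 21.4 against 13.3 ± 3.5 FPKM and the cytokine IL36G at 11.9 ± 5.11 against 63.9 ± 6.48. The log2 mean of this list was 4.93 in BAP replicate 3, 5.60 to 5.70 in the other BAP libraries and 5.51 to 5.65 in vehicle. Nucleotide excision repair had 3 of 25 higher (CETN2, ERCC4 and XPA) and 0 lower (3 and 0 adjusted over the list alone; list adjusted p = 0.369), with a median below and a mean above 0. Cell division had 5 of 34 higher, including the sliding clamp PCNA (38.2 ± 10 to 81.8 ± 8.82 FPKM), and 1 lower, MCM7 (5 and 1 adjusted over the list alone; list adjusted p = 0.0832). The log2 mean of the cell division list was 3.40 in BAP replicate 3, 2.26 to 2.80 in the other BAP libraries and 2.33 to 2.69 in vehicle. MCM3 (adjusted p = 0.0599) and TYMS (adjusted p = 0.0567) no longer passed without BAP replicate 3, and the list passed without BAP replicate 1 (adjusted p = 0.00729) or 2 (adjusted p = 0.0187).

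Of 48 cytosolic ribosomal protein genes, 24 fell and 0 rose (32 and 0 adjusted over the list alone; list adjusted p = 2.64e-09), for example RPL5 from 1660 ± 417 to 844 ± 167 FPKM and RPS2 from 697 ± 110 to 395 ± 83.4. The mean of the ribosomal list on the log2 scale was 8.77 in BAP replicate 4, inside the vehicle range of 8.76 to 9.08, and 8.06 to 8.32 in the other BAP libraries. Of 16 heat shock genes, 10 fell and 0 rose (12 and 0 adjusted over the list alone; list adjusted p = 6.41e-05), with the chaperone HSPA8 at 1330 ± 141 against 2350 ± 130 FPKM and HSPA1B at 30 ± 11.7 against 76.1 ± 3.33. Of 18 immediate early genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone; list adjusted p = 0.000106), including KLF6 (171 ± 23.7 to 54.5 ± 17.9 FPKM) and ZFP36 (61.2 ± 6.96 to 25.1 ± 3.41). Of 24 cholesterol synthesis genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone; list adjusted p = 0.00718), including INSIG1 (406 ± 86.7 to 217 ± 15.4 FPKM). With an estimated correlation the adjusted p was 0.452 for each of these 4 lists, and after quantile normalization the cholesterol list no longer passed (adjusted p = 0.0613). Unfolded protein response genes (1 higher and 6 lower of 28, list adjusted p = 0.24) and glycolysis and hypoxia genes (2 higher and 5 lower of 26, list adjusted p = 0.113) did not pass. Adjusted over the list alone these counts were 1 and 6, and 2 and 6. The glycolysis and hypoxia list passed without BAP replicate 4 (adjusted p = 0.042) or with no expression filter (adjusted p = 0.0128). The log2 mean of the unfolded protein response list was 6.31 to 6.42 in BAP replicates 1, 2 and 4 and 6.35 to 6.50 in vehicle, with BAP replicate 3 below both ranges, and CEBPB no longer passed without that library (adjusted p = 0.0856). VEGFA, the vascular growth factor, fell from 268 ± 16.6 to 86.9 ± 38.7 FPKM and MT2A, a metallothionein, from 751 ± 165 to 204 ± 105.

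Among tested genes with a symbol, in or out of the lists, the largest increases with no overlap between groups included MIR200C, CDC20B, ALDH3A1, SOX2, MAP3K19, CXCL6, PROM1, TST and ANKRD66. SOX2, an epithelial progenitor transcription factor, rose from 0.932 ± 0.364 to 7.74 ± 3.18 FPKM, and PROM1, a membrane protein of cell protrusions, from 51.9 ± 13.8 to 212 ± 109. MIR200C, a microRNA gene 68 nt long, was listed at 0 in all vehicle libraries and at 56.5, 28.6, 26.6 and 36.5 FPKM in the BAP libraries. MIR200C overlaps U47924.27 on the same strand, so its level may depend on how fragments were divided between these genes. The largest decreases were ITGB3, CAPN14, SEMA7A, FHIT, CHI3L1, IL36G, FST, C11orf96, SPRR2D and FXYD2. ITGB3, an integrin chain, fell from 9.55 ± 2 to 0.482 ± 0.394 FPKM, the calpain CAPN14 from 92 ± 11.2 to 12.9 ± 5.1, and FST, the activin-binding protein follistatin, from 158 ± 15 to 32.5 ± 15.8. Over all tested genes, 1313 were higher and 1835 lower after BAP (3148 at adjusted p under 0.05 by limma, 5142 at unadjusted p under 0.05). Of all tested genes, 22% had no overlap between groups, where chance gives 2.86%. The count was 2039 without vehicle replicate 1 and 2048 without vehicle replicate 4. With library sums set equal over genes of at least 200 nt, a scaling chosen after seeing the data, 69.1% of the changed genes were higher, against 41.7% with the deposited scaling.

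The second comparison asked what DBC changed relative to vehicle, at a dose far below that of BAP. Genes that rose included members of the DNA damage response. RRM2B, the p53-inducible ribonucleotide reductase subunit, rose from 20.8 ± 7.74 to 63.3 ± 9.56 FPKM (log2 change 1.62, SE 0.22, adjusted p = 0.00115), and CDKN1A rose from 215 ± 48.3 to 340 ± 36.7 (log2 change 0.68, SE 0.19, adjusted p = 0.0387). Among AHR-responsive genes, CYP1B1 fell from 194 ± 44.9 to 61.9 ± 2.57 FPKM (log2 change -1.60, SE 0.42, adjusted p = 0.0318) and NQO1 from 468 ± 76.5 to 215 ± 43.7 (log2 change -1.12, SE 0.19, adjusted p = 0.00476). CYP1A1 was at 1.46 ± 0.287 against 9.04 ± 3.51 FPKM, with all DBC libraries below all vehicle libraries, but did not pass (log2 change -1.96, 95% interval -3.82 to -0.11, adjusted p = 0.161). ALDH3A1 was at 26.3 ± 3.59 against 43 ± 6.61 FPKM (log2 change -0.68, 95% interval -1.44 to 0.07, adjusted p = 0.232) and TIPARP at 74.4 ± 5.67 against 101 ± 17 (log2 change -0.43, 95% interval -1.20 to 0.35, adjusted p = 0.491). Over the 8 fits that leave out 1 library, NQO1 passed in 8, CDKN1A in 1 (adjusted p 0.0495 to 0.108) and CYP1B1 in 0 (0.0522 to 0.0849, log2 change -1.75 to -1.48). The error of these tests is pooled over the 3 groups, so it includes the spread from BAP replicate 3. With only the DBC and vehicle libraries in the fit, CYP1A1 (adjusted p = 0.00632), CYP1B1 (adjusted p = 0.00245), ALDH3A1 (adjusted p = 0.0181), NQO1 (adjusted p = 0.00924) and CDKN1A (adjusted p = 0.0417) passed. TIPARP did not (adjusted p = 0.0666). AHRR lay at 0 to 0.468 FPKM in the DBC libraries.

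Of the 12 AHR battery genes, 4 fell and 0 rose after DBC (4 and 0 adjusted over the list alone; list adjusted p = 0.0021), with the amino acid transporter SLC7A5 at 27.1 ± 3.27 against 70.1 ± 10.2 FPKM and UGT1A6 at 22.4 ± 3.61 against 41.4 ± 6.65. Of 25 NRF2 antioxidant genes, 7 fell and 0 rose (11 and 0 adjusted over the list alone; list adjusted p = 7.68e-05), including FTL, the ferritin light chain, from 3270 ± 439 to 1290 ± 201 FPKM and the pentose phosphate enzyme PGD from 1110 ± 320 to 461 ± 69.5. With an estimated correlation the adjusted p was 0.452 for both lists. Xenobiotic oxidation had 2 of 28 higher and 4 lower (3 and 6 adjusted over the list alone; list adjusted p = 0.878), and conjugation and efflux 0 of 21 higher and 1 lower, SULT2B1 (2 and 3 adjusted over the list alone; list adjusted p = 0.694).

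Of 31 p53 target genes, 9 rose and 1 fell after DBC (14 and 3 adjusted over the list alone; list adjusted p = 0.000122, adjusted p = 0.452 with an estimated correlation). Besides RRM2B and CDKN1A, the damage recognition genes XPC and DDB2 rose from 9.8 ± 1.16 to 16.8 ± 2.61 and from 13.8 ± 3.09 to 22.1 ± 1.58 FPKM, and ZMAT3 from 14.6 ± 0.579 to 25.2 ± 1.69. MDM2 was at 292 ± 24.2 against 241 ± 45.3 FPKM (log2 change 0.29, 95% interval -0.27 to 0.85, adjusted p = 0.515). GDF15 fell from 651 ± 144 to 354 ± 57.1 (log2 change -0.86, adjusted p = 0.0416), and passed in 1 of the 8 fits that leave out 1 library (adjusted p 0.0302 to 0.12) and with only the DBC and vehicle libraries in the fit (adjusted p = 0.0272). Of 27 interferon response genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.00157, adjusted p = 0.452 with an estimated correlation), among them IFI6 (6.24 ± 1.64 to 15.7 ± 4.35 FPKM). Cytokine and NF-kB genes had 6 of 28 higher and 2 lower (6 and 4 adjusted over the list alone; list adjusted p = 0.478), with CXCL6 at 39.1 ± 8.1 against 13.3 ± 3.5 FPKM and SAA1, an acute phase protein, at 213 ± 69.4 against 80.9 ± 21.4. The median and mean of this list were below 0 and the test direction upward. Nucleotide excision repair had 2 of 25 higher and 2 lower (2 and 3 adjusted over the list alone; list adjusted p = 0.501). Cell division had 3 of 34 higher, RRM2 and MCM3 among them, and 2 lower, CCNB1 and AURKA (4 and 2 adjusted over the list alone; list adjusted p = 0.911, with a median and mean below 0 and a test direction upward).

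Ribosomal protein genes fell after DBC too, with 24 of 48 lower and 0 higher (32 and 0 adjusted over the list alone; list adjusted p = 2.55e-17, adjusted p = 0.452 with an estimated correlation). RPS20 fell from 1850 ± 244 to 318 ± 71.5 FPKM, RPL30 from 1020 ± 159 to 221 ± 38.6 and RPS18 from 2250 ± 187 to 806 ± 158. Ciliated markers had 3 of 38 higher and 0 lower (3 and 0 adjusted over the list alone; list adjusted p = 8.88e-05, adjusted p = 0.557 with an estimated correlation), including FOXJ1, the regulator of motile cilia, from 4.92 ± 2.22 to 14.6 ± 5.38 FPKM. The ciliated mean on the log2 scale was 4.82 in DBC replicate 1 and 4.05 to 4.43 in the other DBC libraries, inside the vehicle range of 3.66 to 4.58. Basal markers had 6 of 24 lower and 0 higher (10 and 0 adjusted over the list alone; list adjusted p = 0.00151, adjusted p = 0.452 with an estimated correlation), including TP63, the basal cell transcription factor, from 196 ± 32.8 to 102 ± 17.4 FPKM and ITGB4 from 576 ± 94.9 to 193 ± 62.5. Secretory markers had 1 of 27 higher and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.899, with a median and mean below 0 and a test direction upward).

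Squamous genes had 8 of 25 lower, including SPRR3 (768 ± 38 to 294 ± 149 FPKM) and KRT16, and 1 higher (9 and 1 adjusted over the list alone; list adjusted p = 0.00697, adjusted p = 0.615 with an estimated correlation). The squamous mean was 5.61 in DBC replicate 4, inside the vehicle range of 5.60 to 5.82, and 5.02 to 5.23 in the other DBC libraries. Matrix and mesenchymal genes had 5 of 28 lower and 0 higher (6 and 1 adjusted over the list alone; list adjusted p = 0.00599, adjusted p = 0.452 with an estimated correlation), led by TGFB1, a growth factor (69.8 ± 9.07 to 15.3 ± 2.8 FPKM), and PLAUR, the urokinase receptor (51.1 ± 6.21 to 14.2 ± 5.96). Desmosomal genes had 2 of 13 lower, DSC3 and DSP, and 0 higher (2 and 0 adjusted over the list alone; list adjusted p = 0.02, adjusted p = 0.452 with an estimated correlation). The desmosomal list no longer passed without vehicle replicate 2 (adjusted p = 0.0638), after quantile normalization (0.124), with equal sums (0.126, median change -0.01 against -0.30) or with a mean of at least 5 FPKM (0.0509). Cholesterol synthesis had 7 of 24 lower and 0 higher (8 and 0 adjusted over the list alone; list adjusted p = 0.00419, adjusted p = 0.452 with an estimated correlation), with SQLE, squalene epoxidase, at 110 ± 11 against 212 ± 41.9 FPKM. Immediate early genes had 2 of 18 lower, MYC and ZFP36, and 0 higher (7 and 0 adjusted over the list alone; list adjusted p = 0.00176, adjusted p = 0.452 with an estimated correlation). Unfolded protein response genes had 3 of 28 lower and 0 higher (4 and 0 adjusted over the list alone; list adjusted p = 0.00628, adjusted p = 0.528 with an estimated correlation), among them the chaperones HSP90B1 and PDIA6. The unfolded protein response list no longer passed after quantile normalization (adjusted p = 0.298) or with library sums set equal over genes of at least 200 nt (adjusted p = 0.0831). With those equal sums, 0 unfolded protein response genes were lower and 1 was higher, and likewise 0 immediate early genes were lower and 1 was higher. Junction genes (2 of 30 higher, 4 lower, list adjusted p = 0.168), heat shock genes (0 of 16 higher, 3 lower, list adjusted p = 0.165), glycolysis and hypoxia genes (0 of 26 higher, 3 lower, list adjusted p = 0.24) and fibroblast markers (0 of 5 higher, 0 lower, list adjusted p = 0.899) did not pass. Adjusted over the list alone their higher and lower counts were 2 and 6, 0 and 4, 0 and 3, and 0 and 0.

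**Figure D3:**
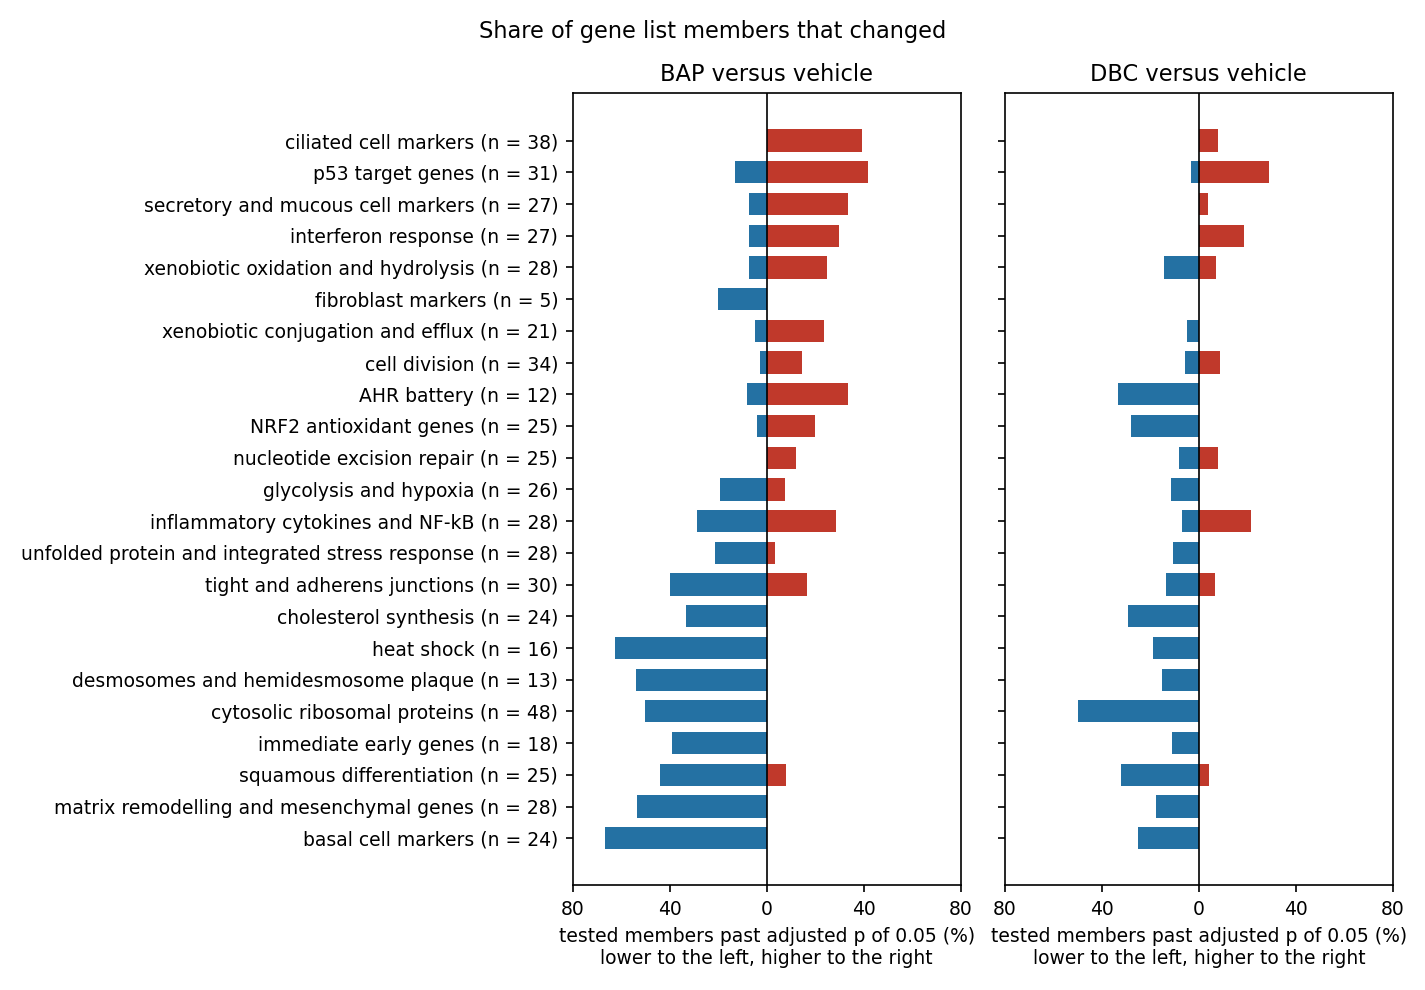
Percent of the tested members of each gene list (n beside its name) that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 by limma, after BAP and after DBC. Of the 24 basal markers 16 were lower after BAP and 6 after DBC, and of the 48 ribosomal protein genes 24 were lower after each. The error of these calls is pooled over all groups, which affects how many members pass for each compound.

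The largest increases after DBC without overlap between groups were INPP5D, RRM2, SAA4, CDC20B, a row named Metazoa_SRP (a copy of the signal recognition particle RNA), the pseudogene RPL23AP64, GPAA1, CLTB, SLFN13 and RRM2B. INPP5D, an inositol phosphatase, rose from 21.2 ± 3.45 to 112 ± 13.5 FPKM (log2 change 2.36, SE 0.21, adjusted p = 9.02e-05), RRM2 from 6.13 ± 1.94 to 25.8 ± 11.2 and SLFN13 from 7.93 ± 1.99 to 26.7 ± 5.15. The largest decreases were all small structured RNAs, namely SNORD127, SNORD26, SNORD18A, RNU5E-1, SNORA7A, SNORA62, SNORD55, SNORD3A, RN7SK and SNORD3C. SNORD3A, the U3 RNA of ribosomal RNA processing, was at 1160 ± 272 FPKM against 20900 ± 12300, and SNORD127, SNORD18A, SNORA7A, SNORA62 and SNORD3C were listed at 0 in all DBC libraries. Genes of short RNAs (under 200 nt) took 1.78% ± 0.695 of the summed FPKM in DBC against 8.35% ± 3.13 in vehicle (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest the design allows). In total 544 genes were higher and 1010 lower (1554 by limma, 3893 at unadjusted p under 0.05), and 21.3% of all tested genes had no overlap between groups (2.86% by chance). The count fell to 655, 813 and 716 without vehicle replicates 1, 3 and 4 and to 652, 581 and 882 without DBC replicates 1, 3 and 4. With only the DBC and vehicle libraries in the fit it was 2133. The BAP count with only the BAP and vehicle libraries was 2210, against 3148 with all libraries. The gap between the compounds in these counts therefore depends on pooling the error over all groups. The DBC count was 809 with no expression filter, 2981 with library weights and 2372 with equal sums over genes of at least 200 nt. The share of changed genes that were higher was 35% as deposited, 55.8% after quantile normalization and 82.3% with those equal sums, which moved the median change of all genes from -0.03 to 0.23.

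The third comparison set the compounds against each other. Their doses differed, so the values below stand side by side without a matched dose. CYP1A1 was at 1.46 ± 0.287 FPKM after DBC and 179 ± 125 after BAP (log2 difference -5.35, 95% interval -7.20 to -3.50, adjusted p = 0.00208), and CYP1B1 at 61.9 ± 2.57 and 622 ± 382 (-3.02, 95% interval -3.93 to -2.11, adjusted p = 0.00114). ALDH3A1 differed by -2.96 (95% interval -3.71 to -2.20, adjusted p = 0.000466) and NQO1 by -2.10 (95% interval -2.51 to -1.68, adjusted p = 8.33e-05). CDKN1A was higher after DBC by 0.64 (95% interval 0.23 to 1.05, adjusted p = 0.0381). MDM2 differed by 0.02 (95% interval -0.54 to 0.58, adjusted p = 0.972), GDF15 by 0.02 (95% interval -0.51 to 0.55, adjusted p = 0.977) and TIPARP by -0.59 (95% interval -1.37 to 0.19, adjusted p = 0.292). Without BAP replicate 3 the difference was -6.57 for CYP1A1 (SE 0.27, adjusted p = 4.11e-07), -3.57 for CYP1B1 (adjusted p = 1.03e-05) and -1.07 for TIPARP (adjusted p = 0.00416). CDKN1A no longer passed (0.54, adjusted p = 0.094). With 1 library left out, CDKN1A passed in 1 of 8 fits (adjusted p 0.0253 to 0.0941), and CYP1A1, CYP1B1, ALDH3A1 and NQO1 passed in 8.

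By gene list, 6 of 12 AHR battery genes and 13 of 25 NRF2 antioxidant genes were lower after DBC than after BAP, and 0 of either were higher (6 and 0, and 16 lower and 1 higher, adjusted over the list alone; list adjusted p = 0.000106 and 9.44e-07). Both had an adjusted p of 0.452 with an estimated correlation. The peroxiredoxin PRDX1 was at 302 ± 21.4 FPKM after DBC and 607 ± 129 after BAP. Xenobiotic oxidation had 10 of 28 lower, including EPHX1 (25.1 ± 1.06 and 49.8 ± 10.6 FPKM), and 1 higher, CYP3A5 (63.8 ± 16.8 and 16.1 ± 2.16 FPKM), with 11 and 2 adjusted over the list alone (list adjusted p = 0.00157). Conjugation and efflux had 4 of 21 lower, including GSTA1, and 0 higher (7 and 0 adjusted over the list alone; list adjusted p = 0.0124). The adjusted p with an estimated correlation was 0.452 for these 2 lists, and the conjugation list no longer passed without BAP replicate 4 (adjusted p = 0.0526) or with no expression filter (adjusted p = 0.0713).

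Basal markers had 6 of 24 higher after DBC than after BAP, including ITGA3 (463 ± 89.6 and 215 ± 42.2 FPKM) and the cytokine IL33 (23.4 ± 6.89 and 6.73 ± 4.16), and 0 lower (8 and 0 adjusted over the list alone; list adjusted p = 0.00144). Matrix genes had 10 of 28 higher, including CYR61 (136 ± 13.7 and 45.3 ± 12.1 FPKM) and MMP14 (130 ± 21.6 and 56.3 ± 12.6), and 1 lower, TGFB1 (11 and 2 adjusted over the list alone; list adjusted p = 0.000539). Heat shock genes had 7 of 16 higher, including HSPA8 (2540 ± 353 and 1330 ± 141 FPKM), and 1 lower (8 and 1 adjusted over the list alone; list adjusted p = 0.00254). Desmosomal genes had 2 of 13 higher, PPL and PLEC, and 0 lower (2 and 0 adjusted over the list alone; list adjusted p = 0.0181). With an estimated correlation the adjusted p was 0.452 for each of these 4 lists. Ciliated markers had 3 of 38 lower and 0 higher (2 and 0 adjusted over the list alone; list adjusted p = 0.00335, adjusted p = 0.685 with an estimated correlation), including SNTN (48.2 ± 15.1 and 96.3 ± 14 FPKM). Secretory markers had 7 of 27 lower, including MUC1 and MSMB, and 1 higher, CLCA4 (12 and 1 adjusted over the list alone; list adjusted p = 0.00628, adjusted p = 0.528 with an estimated correlation). Ribosomal protein genes had 9 of 48 lower and 1 higher (9 and 2 adjusted over the list alone; list adjusted p = 0.0337, adjusted p = 0.778 with an estimated correlation), and after quantile normalization 7 lower and 7 higher (list adjusted p = 0.312). Without BAP replicate 3 the ciliated (adjusted p = 0.117), secretory (adjusted p = 0.0629) and desmosomal (adjusted p = 0.0564) lists no longer passed. PLEC no longer passed without that library (adjusted p = 0.0959). The desmosomal list was also lost without BAP replicate 1 (adjusted p = 0.0633) or DBC replicate 4 (adjusted p = 0.0502). The ribosomal list was lost without BAP replicate 4 (adjusted p = 0.656) or without DBC replicates 1, 3 or 4 (adjusted p = 0.0754, 0.138 and 0.0688), and with no expression filter (adjusted p = 0.0683).

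Of 31 p53 targets, 3 were higher after DBC than after BAP (BTG2, CDKN1A and PHLDA3) and 2 lower (POLH and TRIAP1). Without BAP replicate 3, PHLDA3 no longer passed (adjusted p = 0.0926). The counts adjusted over the list alone were 3 and 2. The list did not pass (list adjusted p = 0.667). Interferon response genes (0 of 27 higher, 1 lower, list adjusted p = 0.878), cytokine and NF-kB genes (2 of 28 higher, 4 lower, S100A8 and S100A9 among them, list adjusted p = 0.273), nucleotide excision repair (0 of 25 higher, 3 lower, list adjusted p = 0.781) and cell division (1 of 34 higher, 3 lower, list adjusted p = 0.105) did not pass either. Adjusted over the list alone these were 0 and 1, 4 and 4, 0 and 3, and 0 and 3. The cell division list passed without BAP replicate 1 or 2 or DBC replicate 3 (adjusted p = 0.0106, 0.0288 and 0.0115). Squamous genes (3 of 25 higher, 3 lower, list adjusted p = 0.237), junction genes (6 of 30 higher, 3 lower, list adjusted p = 0.165), immediate early genes (3 of 18 higher, 0 lower, list adjusted p = 0.0836), unfolded protein response genes (2 of 28 higher, 5 lower, list adjusted p = 0.352), cholesterol synthesis (2 of 24 higher, 2 lower, list adjusted p = 0.89, with a median above and a mean below 0), glycolysis and hypoxia (4 of 26 higher, VEGFA among them, 1 lower, list adjusted p = 0.589) and fibroblast markers (0 of 5 higher, 0 lower, list adjusted p = 0.731) gave no list call. Adjusted over the list alone the counts were 6 and 3, 8 and 5, 4 and 0, 2 and 5, 2 and 2, 4 and 1, and 0 and 0. The squamous list passed without BAP replicate 4 (adjusted p = 0.0157), and the unfolded protein response list without BAP replicate 3 (adjusted p = 0.0247). The immediate early list passed without BAP replicate 2 or 4 or DBC replicate 3 (adjusted p = 0.046, 0.0169 and 0.0355). With no expression filter the squamous, junction and immediate early lists passed (adjusted p = 0.0424, 0.0212 and 0.0229).

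The largest excesses of DBC over BAP without overlap were TGIF2-C20orf24, PEG10, CAPN14, HSPA6, CHI3L1, USP35, SKIV2L, CYP3A5, CLCA4 and CEACAM7. PEG10, a gene of retrotransposon origin, was at 66.3 ± 21.7 FPKM after DBC and 13.6 ± 3.88 after BAP, and CAPN14 at 60.1 ± 20.5 and 12.9 ± 5.1. TGIF2-C20orf24 is a read-through annotation that overlaps TGIF2 and C20orf24, was listed at 0 in all BAP libraries and at 13.1, 16.4, 11.2 and 21.4 FPKM after DBC. Its level depends on how fragments were divided among the 3 genes. The largest deficits were SNORD127, SNORD26, RNU5E-1, SNORD104, SNORD42A, SNORD59A, SNORA7A, MIRLET7G, SNORA61 and SNORD55, all under 200 nt. Without BAP replicate 3, SNORD42A (adjusted p = 0.0746) and SNORD59A (adjusted p = 0.0661) no longer passed. Short RNA genes took 1.78% ± 0.695 of the FPKM after DBC and 11.8% ± 5.22 after BAP (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest possible). Overall counts were 1176 higher and 1117 lower (2293 by limma, 4448 at unadjusted p under 0.05), and 19.4% of all tested genes had no overlap between groups (2.86% by chance). The count was 1464 without DBC replicate 2 and 1400 without DBC replicate 4, and 65.3% of the changed genes were higher with equal sums over genes of at least 200 nt, against 51.3% as deposited.

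The changes against vehicle were then compared across compounds. In both comparisons 228 genes were higher, among them CDC20B, CXCL6, ZMAT3 and CCNO, and 422 were lower, among them ITGA6, NGFR, INSIG1, GDF15 and RPS2. Independent lists of these sizes would share 49.2 and 128 genes. In simulations of all 12 libraries without any change, with the simulated vehicle shared by both comparisons, 0.01 and 0 genes were shared on average. With no change simulated few genes can be called at all, so that overlap was near 0 in advance. It does not measure what the shared vehicle adds to the overlap. Genes that were higher after BAP and lower after DBC numbered 18 (91.4 for independent lists), with CYP1B1, NQO1 and CLDN10 among them, and 12 went the other way (68.8 for independent lists), among them PEG10, SKIV2L and STAT6. Across the 14514 genes, which are not independent replicates, the log2 changes correlated at r = 0.428 (simulated unchanged groups 0.499, range 0.458 to 0.537) with a covariance of 0.149 against a simulated 0.0501. When the vehicle libraries were divided 2 and 2 between the comparisons, the correlation was 0.184 to 0.28 over the 6 divisions, the covariance 0.0776 to 0.109, and 16 to 40 genes were higher and 45 to 83 lower in both. The 228 shared increases became 81, 135 and 88 without vehicle replicates 1, 3 and 4 and 99, 79 and 136 without DBC replicates 1, 3 and 4. The 422 shared decreases became 147, 209, 149, 181, 162 and 260 in the same order.

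Few markers of cell types not named in the labels passed the expression filter. Of 20 leukocyte and endothelial markers, 3 passed (CD68, CD14 and LYN, with CD68 at 37.6 ± 3.41 FPKM in vehicle and 18.5 ± 9.05 after BAP), of 18 rare epithelial markers 4, and of 9 metallothionein genes 4, too few for a list test. After BAP, 2 of the 3 leukocyte and endothelial markers, 1 of the 4 rare epithelial markers and 1 metallothionein (MT2A) were lower, and 1 rare epithelial marker, LRMP, was higher. After DBC, LYN and MT2A were lower and no rare epithelial marker passed. All 13 mitochondrially encoded protein genes were listed at 0 in every library, as a failed estimate would be, so they carry no information on mitochondrial RNA.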

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

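The tests on BAP replicate 3 and on ribosomal protein pseudogenes, and the depth comparison for short RNAs, were chosen after the result had been seen. The short RNA test on histone genes was added after RN7SK and SNORD3A had been seen but before the histone values, and the others were chosen before their results were seen. The gap of each group's most distant library was measured on log2(FPKM + 1), a scale chosen knowing that CYP1A1 in BAP passes on it and not on FPKM. A gap passes above Dixon's 95% limit for 4 libraries, which chance exceeds in about 1 in 20 groups. Of 460 groups of 4 libraries over the genes named in the text, 30 passed, where chance gives 23, and 4 of these had BAP replicate 3 as the distant library.

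BAP replicate 3 was lowest of its group for CYP1A1 (gap 0.862, 6.96 FPKM against 182 to 301), for CYP1B1-AS1 (0.887, 15.2 against 69.3 to 83.8) and for PHLDA3 (0.85, 14.5 against 19.9 to 21), and highest for FHIT (0.847). BAP replicate 4 was highest for CEACAM7 (0.987), PPL (0.849), RPS2 (0.859) and RNU5E-1 (0.901, 3460 FPKM against 272 to 350), and lowest for RPL23AP64 (0.921). BAP replicate 2 was lowest for TGIF2 (0.874). In DBC, replicate 1 was highest for ALDH1A1 (0.888). Replicate 2 was highest for ITGB4 (0.936), MT2A (0.969) and TGFB1 (0.887) and lowest for GSTA1 (0.891). Replicate 3 was highest for PIGR (0.899) and SOX2 (0.958) and lowest for FXYD2 (0.866, listed at 0), and replicate 4 was highest for SPRR2D (0.879). In vehicle, replicate 3 was highest for TST (0.857), replicate 4 lowest for USP35 (0.963) and replicate 1 lowest for SNORA61 (0.89, listed at 0). Where the other 3 libraries were listed at 0 the gap is 1 by construction, as for SNORD42A, SNORD59A and RNU5E-1 in DBC and for rows named Metazoa_SRP in each group. A further Metazoa_SRP row had DBC replicate 1 lowest (0.895).

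BAP replicate 3 lacked the rise of CYP1A1 and CYP1B1. A vehicle library under a BAP label would lie near the vehicle mean, at 0 on a scale where the other BAP libraries lie at 1. Over the genes changed in a fit without it, with the AHR battery left out, its median position was 1.14, which argues against that label error. A weaker response across the changed genes outside that battery is argued against as well. Its position lay 0.434 above the lowest of the other BAP libraries (0.864, 0.747 and 0.706, likewise without the AHR battery). The log2 means of the AHR battery, NRF2 and p53 lists in BAP replicate 3 (5.53, 6.15 and 4.80) lay inside or below the vehicle range. The 9.16 M (mega) fragments of BAP replicate 3, the most in the group, argue against low depth, and no biological explanation was tested.

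Short RNA genes were lower in the DBC libraries. Lower expression of their host genes is argued against, since 89 hosts had a median log2 change of -0.001 (DBC minus BAP) where their 119 snoRNAs had -1.31. Low depth is argued against by vehicle replicates 1 and 3, with 9.9% and 6% of FPKM in short RNA genes at a depth inside the DBC range, against at most 2.5% in DBC. For a loss of short molecules, noncoding genes of at least 200 and under 400 nt stood at -0.131 (95% interval -0.276 to 0.017). That change did not reach the cut set beforehand. For less carry-over of RNA without a poly-A tail, 14 histone genes stood at -0.429 (95% interval -0.899 to -0.022), which reached the cut. Neither explanation is settled by these values. Against vehicle the histone median was 0.86 after BAP and 0.20 after DBC, so the histone difference is not a loss relative to vehicle, and an effect of DBC itself was not tested.

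Ribosomal protein transcripts were lower after both compounds, with a median log2 change of -0.58 (BAP) and -0.76 (DBC), except in BAP replicate 4, whose list mean of 8.77 lay inside the vehicle range of 8.76 to 9.08. Scaling alone is argued against, since under median-ratio scaling and quantile normalization the medians stayed at or below -0.352 and -0.438. Of 10000 random lists matched on length and level 0% were as low for either compound, although their typical medians, -0.24 and -0.34, were below 0 as well. The lowest random medians, -0.555 and -0.719, came near the list. Ribosomal protein genes move together (estimated correlation 0.492), which random lists need not. The 0% therefore does not measure how rare such a median is for genes that move together. The 29 ribosomal protein pseudogenes above the expression filter gained -0.572% and -0.348% of what the genes lost, a loss and not a gain. Copies below the filter were not summed. A response to the compounds is a candidate explanation, as a hypothesis found on these data, while a batch difference, for which no label is given, stays open.

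The splits of the 8 libraries of a comparison into 4 and 4 were counted, 35 each with the real one included. Only 1 split, the real one, called as many genes in each comparison. BAP versus vehicle gave 3148 genes (at most 61 in other splits), DBC versus vehicle 1554 (at most 2) and DBC versus BAP 2293 (at most 1). A share of 1 in 35 is the smallest these splits can give. The other splits mix both groups in each part, which widens the spread and lowers their counts. The splits show that the libraries differ by group, and cannot tell treatment from batch.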

How the results depend on the processing

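Among the settings, those with only protein-coding genes of at least 200 nt and with equal sums over genes of at least 200 nt were chosen after seeing the data. The counts for BAP versus vehicle and DBC versus BAP stayed within 1.5 times under the settings that keep all libraries. DBC versus vehicle gave 809 genes with no filter, where more genes are tested, 2981 with library weights and 2372 with equal sums. Leaving out each library in turn, where fewer samples remain, gave 2039 to 3103 genes (BAP versus vehicle), 581 to 1423 (DBC versus vehicle) and 1400 to 2340 (DBC versus BAP). With a correlation estimated per list, 0 of 69 list tests passed with camera (6 at an unadjusted p under 0.05).

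The covariance of the changes in BAP and DBC was 0.277 with a pseudocount of 0.1, 0.089 with no filter and 0.088 with the vehicle libraries split, where the correlation was 0.216. Genes higher in both numbered 97 with no filter, 404 with library weights, 795 with equal sums and 31.5 on average with the vehicle libraries split, and 79 to 255 with each library left out. Genes lower in both numbered 207, 783, 133 and 63.8 in that order, 204 after quantile normalization, and 147 to 513 with each library left out. With the vehicle libraries split, independent lists would share 5.36 higher and 18.8 lower genes on average. The causes were not tested beyond the number of genes or samples.

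The replicate block gave 3192, 1624 and 2434 genes and 38 list calls. Pairing by number was partial at most. Of 12 pairs with the same number, 3 correlated over 0.1 after removal of the group means (-0.09 to 0.23, median -0.002). Other pairs correlated at -0.266 to 0.158. The highest values were for vehicle and BAP replicates 2 (0.23) and 3 (0.199). Of 12 libraries, 6 correlated best with a library of their own number. A link between some libraries of the same number therefore stays open.

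Over 371 results of named genes and 7363 values under other settings, 6760 kept their side of the threshold, 527 no longer passed, 76 newly passed and 0 reversed. Over 69 list tests and 1377 values these were 1325, 22, 30 and 0. Reversal was scored only where a value compared passed. Values that passed in neither fit therefore count as kept even where their sign changed. TIPARP in BAP versus vehicle, for example, ranged from -0.12 to 0.64 with 1 library left out. Depth limits the genes near 1 FPKM and under 200 nt.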

Other observations

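The genes in this part were chosen after their values were seen, and no explanation was tested for them. Among genes that passed in both comparisons against vehicle with opposite signs, G3BP1, a stress granule protein, stood at 73.8 ± 2.42 FPKM in vehicle, 104 ± 20.8 after BAP and 45.6 ± 2.72 after DBC (SD, n = 4), and CYB5A, cytochrome b5, at 68.2 ± 3.44, 110 ± 19.6 and 43 ± 8.26. In the other direction, STAT6, a signalling transcription factor, stood at 171 ± 31, 95 ± 20.6 and 267 ± 31.6 FPKM, and SKIV2L, an RNA helicase, at 37.5 ± 5.87, 19.8 ± 6.21 and 75.2 ± 12.4.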
